A study of Triticum aestivum with 6 samples.

How the data were processed

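Total RNA of 6 wheat crown samples, 3 inoculated with Fusarium pseudograminearum and 3 mock-inoculated, was labelled with biotin and hybridised to the Affymetrix GeneChip Wheat Genome Array by a service facility, per the labels' protocols. The sample titles give the group and the replicate number. The authors' deposited table, the series' value table, holds 61290 rows and 1 column per array, and its values are ratios: all lie above 0, and the median of a row over the 6 arrays is 1, within 0.0001, in 95.7% of rows. In the other rows the median is below 1, as it would be if a floor had stood in for a low median. Of the tested probe sets, 2654 (4.34%) were of this kind. They are called probe sets divided by a floor below, although the floor itself was not tested. The log base, background correction, summary of the probes and scaling between arrays are not given in the sources used here. That the values are linear follows from the row medians, which are exact on the linear scale, and the array medians lie close to 1. Scanner files were not used here. Because each ratio is centred on its own row, no probe set's level can be set against another's, low signal cannot be filtered, and differences between arrays are unaffected by the centring. No more than 0.23% of values were identical between any 2 arrays, so no array was treated as a copy.

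The ratios were converted to log2 and fitted with limma 3.58.1 in R 4.3.3 (lmFit with the group as the factor, eBayes), and p-values were adjusted by Benjamini and Hochberg over 61179 probe sets, with 111 Affymetrix control probe sets left out. All 6 arrays entered the fit with no covariate. Calls were made at an adjusted p under 0.05, with a second count at an absolute log2 difference of at least 1. The design, written before the data were examined, had assumed that the mean over arrays would measure expression and used a trend on that mean in eBayes. In row-centred ratios it does not, so the trend was left out before any test was run and the fit with it was kept as an alternative. Planned filters on low mean signal, a list of members above a signal percentile and changes of the pseudocount were not run, since they need levels. The methods were tested on simulated data with the real residual spread and row centring. For the comparison of inoculated with mock arrays over 61179 simulated probe sets, 27 of 50 changes of 1.5-fold, 45 of 50 of 2-fold, 50 of 50 of 4-fold and 49 of 50 of 8-fold were recovered, and 6 unchanged probe sets were called. Each simulated change was equal on all inoculated arrays, with independent normal noise. The real rises were unequal between these arrays, so the shares recovered do not carry over to them.

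Probe sets were named through GEO's platform annotation, which pairs 1273 of them with 1 gene each, none with several, and leaves 59906 unnamed here. Of the 1273, 1272 were found by gene number in the RefSeq gene table of the assembly IWGSC CS RefSeq v2.1, which gave synonyms. Only 200 probe sets of 102 genes have a symbol or synonym beyond a locus number. No coordinates are given because the array names no build. Of 33 gene lists fixed before the data were examined as patterns on gene names, 7 matched any probe set and none matched more than 3, against the minimum of 5 for a test. They were replaced by 11 lists built from the symbols and synonyms after the values of these genes had been seen, so their tests are not independent of the data. These were tested with camera at a preset correlation of 0.01 and again with an estimated one. The named genes follow a rule fixed before the data were examined: the 12 largest rises and the 12 largest falls among called probe sets with 1 gene and no overlap between groups, 1 probe set per gene, and in each list the 3 largest called changes or, if none, the member with the smallest p. The rule also asked for a description of the gene, which the annotation lacks and which only PR5 could be said to meet. After the values had been seen this condition was dropped, so locus numbers are given, with 2 unnamed probe sets in each direction. Other probe sets and genes were named after their values were seen.

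Alternatives were quantile normalization, median centring, the trend with and without robust estimation, array weights, a replicate block, leaving out cross-matching probe sets, 1 probe set per gene, and leaving out each array in turn. After seeing the data, fits without probe sets divided by a floor and without both arrays numbered 1 were added. Figures were drawn with matplotlib 3.10.9.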

Results

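Gene expression was measured in the crown of bread wheat (Triticum aestivum) of the variety Kennedy after the stem base had been inoculated with Fusarium pseudograminearum, a fungus that causes crown rot, or with water. Seedlings were 2 weeks old and the crown was taken 24 hours after inoculation. There were 3 inoculated and 3 mock-inoculated samples, each a pool of 2 cm of stem base from about 20 plants, and each was hybridised to 1 Affymetrix GeneChip Wheat Genome Array, which reads 1 colour. The labels do not say whether the pools were grown or inoculated on separate occasions, so the p-values measure the spread between these pools and arrays. The deposited value of a probe set was a ratio to its own median over the 6 arrays, which keeps differences between arrays and drops the expression level. Medians of the 6 arrays lay between 0.99 and 1.002. Arrays have no read depth, and their number, 3 per group, limits the precision.

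The comparison between inoculated and mock-inoculated crowns asked which probe sets of the wheat array differed in signal at 24 hours. Binding of fungal RNA to wheat probe sets could not be tested with the table and annotation used here, so a rise is that of a probe set's signal, and its origin in wheat was not tested. Of 61179 probe sets, 214 were higher and 10 were lower in the inoculated samples (limma, Benjamini-Hochberg adjusted p under 0.05). The median rise was 2.22-fold and the largest was 23.0-fold, whereas the largest fall was 2.14-fold. At 2-fold or more, 119 probe sets were higher and 1 was lower, and 42 of the rises reached 4-fold, 28 reached 8-fold and 8 reached 16-fold. The largest rises were those of probe sets Ta.21556.1.S1_x_at (log2 difference 4.52 ± 0.29 SE, n = 3 per group) and Ta.3133.1.S1_x_at (4.50 ± 0.42), neither of which has a gene in the annotation used here. The largest falls were those of Ta.23025.1.A1_at (log2 difference -1.10 ± 0.12 SE) and Ta.28496.1.A1_at (-0.73 ± 0.10), also without a gene. After quantile normalization Ta.21556.1.S1_x_at had a log2 difference of 3.19, Ta.3133.1.S1_x_at 3.33 and Ta.23025.1.A1_at -1.95 (limma adjusted p = 0.060), so the sizes depended on the normalization. Quantile normalization gives all arrays one distribution of ratios, so it also alters the extremes that a response would produce. Which sizes are nearer the true ones was not tested. Both rises passed the threshold whichever single array was left out (limma adjusted p of at most 0.0071 and 0.030). Ta.23025.1.A1_at lost it without mock replicate 2 or inoculated replicate 2 (at most 0.058), and Ta.28496.1.A1_at without any 1 mock replicate or inoculated replicate 2 (at most 0.11). For all 224 probe sets every inoculated array lay beyond every mock array. Over all probe sets the groups were apart in 12.2%, against 10% by chance. The count depended on single arrays. It was 87 without mock replicate 1, 42 without mock replicate 2, 54 without mock replicate 3, 491 without inoculated replicate 1, 63 without inoculated replicate 2 and 185 without inoculated replicate 3.

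PR5 (LOC543292), a thaumatin-like pathogenesis-related protein, was 19.3-fold higher in the inoculated crowns. Its log2 ratio was -2.74 ± 0.34 (SD, n = 3) in the mock samples and 1.54 ± 0.59 (SD, n = 3) in the inoculated samples, a difference of 4.27 ± 0.26 (SE; limma adjusted p = 0.00034). After quantile normalization the difference was 2.97. It was the only gene past the threshold for which the annotation holds a name other than a locus number. The annotation assigns 1273 of the tested probe sets to 771 genes, and 25 of these probe sets passed the threshold, 23 higher and 2 lower. With adjustment over these 1273 probe sets only, 31 passed. After PR5, the largest rises among genes with a locus number were 4.36-fold for LOC543492, 3.95-fold for LOC542839, 3.71-fold for LOC543330 and 3.46-fold for LOC543422. LOC543492 went from a log2 ratio of -0.88 ± 0.07 (SD, n = 3) to 1.25 ± 0.68, and LOC542839 from -1.01 ± 0.19 to 0.98 ± 0.44. LOC543235 rose 3.10-fold, with the second-smallest adjusted p of the annotated genes (limma adjusted p = 0.0014). LOC543097 rose 2.98-fold, LOC542887 2.47-fold, LOC543342 2.34-fold, LOC543287 2.25-fold, LOC543313 2.22-fold and LOC542826 2.12-fold. The 2 annotated genes that fell changed less. LOC542941 fell by 0.62 ± 0.10 (SE) on the log2 scale and LOC543440 fell by 0.51 ± 0.07.

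Of these 14 genes, PR5, LOC542839 and LOC543235 passed the threshold whichever single array was left out, with limma adjusted p of at most 0.0049, 0.038 and 0.019. The other 11 lost the threshold without at least 1 array. LOC543330 and LOC543342 lost it without mock replicate 2 or 3 (limma adjusted p of at most 0.064 and 0.062), LOC542887 without mock replicate 1 or 2 or inoculated replicate 2 (at most 0.076), and LOC543287 without any 1 mock replicate (at most 0.11). LOC543492, LOC543422, LOC543097 and LOC542826 lost it without any 1 mock replicate or inoculated replicate 2 (at most 0.10, 0.077, 0.12 and 0.11). LOC543313, LOC542941 and LOC543440 passed only with all arrays or without inoculated replicate 1 (otherwise at most 0.26, 0.22 and 0.17). With robust estimation in limma and a trend on the mean log2 ratio, PR5 had an adjusted p of 0.061, LOC543330 had 0.10, LOC543097 0.25 and LOC543313 0.32, and the unnamed Ta.21556.1.S1_x_at and Ta.3133.1.S1_x_at had 0.068 and 0.17. In row-centred ratios this mean does not measure expression, which is why the main fit leaves the trend out. The trend alone does not account for most of these losses. PR5, LOC543330, LOC543097 and both unnamed probe sets passed with it and lost the threshold only when robust estimation was added. Robust estimation without the trend was not run. LOC543313 also lost the threshold with the trend alone (limma adjusted p = 0.10) and with median centring (0.0501), and LOC543287 and LOC543440 lost it without both arrays numbered 1 (0.071 and 0.056).

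Where a gene had several probe sets, they did not always move together. All 3 probe sets of LOC543422 rose, by 3.46-fold, 2.11-fold and 1.95-fold. Of the 2 probe sets of LOC543342, Ta.27762.1.S1_x_at rose (log2 difference 1.23) and Ta.27762.1.S2_at had a log2 difference of -0.11 (limma adjusted p = 0.88). LOC606366 had 4 probe sets that were between 1.29-fold and 1.99-fold higher, of which 1 passed the threshold. Probe sets ending in _x_at or _s_at can match several transcripts, and the copies of a gene in the 3 wheat subgenomes can share a probe set, so a locus number stands for the annotation of its probe set.

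**Figure D1:**
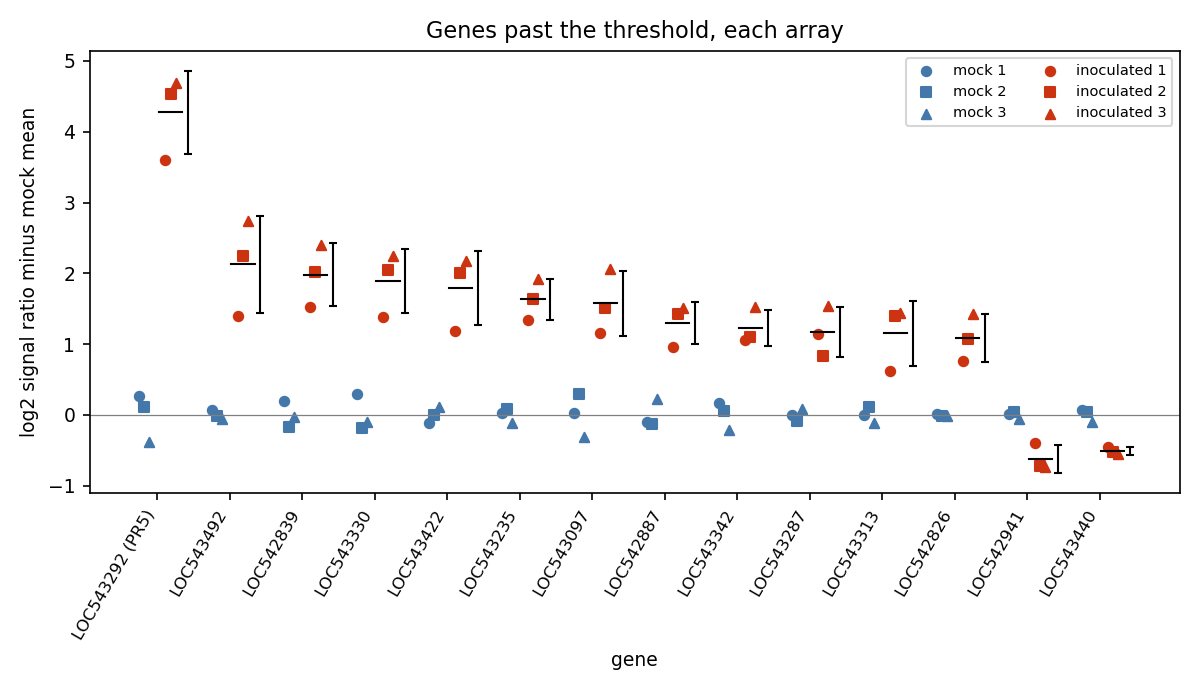
Log2 signal ratio minus the mock mean (vertical axis) for the 12 annotated genes with the largest rises and the 2 that fell (horizontal axis). Points are single arrays, blue for mock and red for inoculated, with the marker giving the replicate number; the black line is the inoculated mean and the bar its SD (n = 3). PR5 (LOC543292) stands apart with a difference of 4.27, and the other rises lie between 1.09 and 2.13.

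Gene groups were compared through 11 lists that were drawn up after the values of these genes had been seen. Core histones H2A and H2B, which package DNA and whose transcripts are abundant in dividing cells, had a median log2 difference of -0.20, with 17 of 18 probe sets (5 genes) below 0. The set test called the list with a preset correlation of 0.01 (camera adjusted p = 1.04e-07 over 11 lists) and did not with an estimated correlation (camera adjusted p = 0.39). None of the 18 passed the limma threshold, either over all probe sets or adjusted over the list alone, and 8 were lower at an unadjusted p under 0.05. H2A-3 (LOC732713) had log2 differences of -0.23 ± 0.07 (SE; limma adjusted p = 0.40) and, on a probe set that can match several transcripts, 0.09 ± 0.10. The call at the preset correlation held whichever single array was left out, with a median between -0.26 and -0.17. Most of the 18 probe sets belong to the genes LOC543184 and LOC732714, so they are not independent readings.

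The other 10 lists did not pass the set test. No signal level is kept for their probe sets, so one that did not change may be expressed evenly or lie at background. Defence proteins outside the thionins (PR5, the peroxidase PER1, the lipid transfer protein LTP3, wheat germ agglutinin WGA2, the xylanase inhibitor XIP-I and wci) had 1 of 9 probe sets higher, that of PR5, both over all probe sets and adjusted over the list alone, and 8 that did not pass. Without inoculated replicate 3 this list and that of grain proteins passed the set test at the preset correlation (camera adjusted p = 0.022 for each). With an estimated correlation, which was run on all arrays only, neither passed (camera adjusted p = 0.39 and 0.72). The median log2 difference of the defence list was 0.04 and its mean 0.49, and camera gave an adjusted p of 0.098. By symbol or synonym no probe set could be assigned to PR1 proteins, beta-1,3-glucanases, chitinases or WRKY factors. Of the 224 called probe sets, 199 had no gene. The defence list therefore does not show whether defence genes outside it changed. None of the 6 probe sets of the thionins, small antimicrobial peptides, passed (median 0.03, camera adjusted p = 0.67); THI1.3 (LOC543413) had log2 differences of 0.19 ± 0.08 (SE; limma adjusted p = 0.69) and 0.03 ± 0.08 on its 2 probe sets. None of the 10 probe sets of serpins and other inhibitor proteins, a list that shares XIP-I with the defence list, passed (median 0.03, camera adjusted p = 0.67), with SER1 (LOC100037548) at -0.10 ± 0.08 and -0.0048 ± 0.09. None of the 10 tubulin probe sets passed, and 8 of them were below 0 (median -0.09, camera adjusted p = 0.063), with Tubb5 (LOC543261) at -0.16 ± 0.07 and its other 3 probe sets between -0.17 and -0.13. LEA, Em and dehydrin proteins, which accumulate on drying, likewise had 8 of 10 probe sets below 0 and none past the threshold (median -0.10, camera adjusted p = 0.089), with the Em gene LOC543480 at -0.22 ± 0.10, -0.14 ± 0.11 and 0.02 ± 0.08. Without probe sets divided by a floor, tubulins and LEA-type proteins passed the set test (camera adjusted p = 0.045 and 0.040), and with 1 probe set per gene the LEA-type proteins passed (0.035), all at the preset correlation. With an estimated correlation, run on all probe sets only, neither list passed (camera adjusted p = 0.39 for each).

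Lists that mark other cell states or tissues also did not pass, and none of their probe sets passed the limma threshold over all probe sets or adjusted over the list alone. For nuclear-encoded photosynthesis proteins, markers of green leaf-sheath cells, none of the 9 probe sets passed. Their median log2 difference was 0.00014 and their mean -0.035, and camera, which gave a downward direction, had an adjusted p of 0.67; petC, the Rieske protein of the cytochrome complex, was at -0.26 ± 0.08 (SE; limma adjusted p = 0.39) on one probe set and 0.01 ± 0.06 on the other. With array weights the first passed, at -0.34 (limma adjusted p = 0.015). The 28 probe sets of rbcL, the large subunit of Rubisco, had log2 differences between -0.22 and 0.27 with a median of -0.01 (camera adjusted p = 0.76). Gliadins, glutenins and avenin-like proteins of the grain had a median of 0.04 over 17 probe sets (camera adjusted p = 0.38), with the avenin-like LOC100125692 at 0.15 ± 0.07 and its other 3 probe sets at 0.16, 0.08 and -0.06. The 9 probe sets of translation factors and ribosomal proteins had a median of -0.02 (camera adjusted p = 0.90), with Eif4B (LOC543417) at -0.13 ± 0.08. Enzymes of fructan, starch and sugar metabolism had a median of -0.01 over 14 probe sets (camera adjusted p = 0.71), with 6-FEH (LOC780575), which degrades fructan, at -0.15 ± 0.07 and its other 2 probe sets at -0.21 and -0.10. At an unadjusted p under 0.05, limma called 1 thionin, 1 tubulin, 1 photosynthesis, 1 grain and 1 LEA-type probe set, and none of the inhibitor, rbcL, translation or sugar lists.

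The rise was not equal on the 3 inoculated arrays. Over the 214 higher probe sets, median log2 rises over the mock mean were 0.85, 1.14 and 1.39 on inoculated replicates 1, 2 and 3. The mock arrays lay between -0.03 and 0.04, near 0 because their own mean was the baseline. Replicate 1 was the lowest inoculated array for 180 of the 214 probe sets. PR5 was also lowest there, with a log2 ratio of 0.86 against 1.80 and 1.95 on inoculated replicates 2 and 3. When the probe sets were chosen without inoculated replicate 1, it lay above every mock array for 433 of the 463 called higher, and its median log2 rise was 0.52 against 0.97 for the other inoculated arrays. Chosen without inoculated replicate 2 or without inoculated replicate 3, all 62 and all 179 probe sets lay above every mock array on the array left out. A mock array left out lay above both other mock arrays for 50 of 82 (replicate 1), 15 of 42 (replicate 2) and 17 of 51 probe sets (replicate 3).

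**Figure D2:**
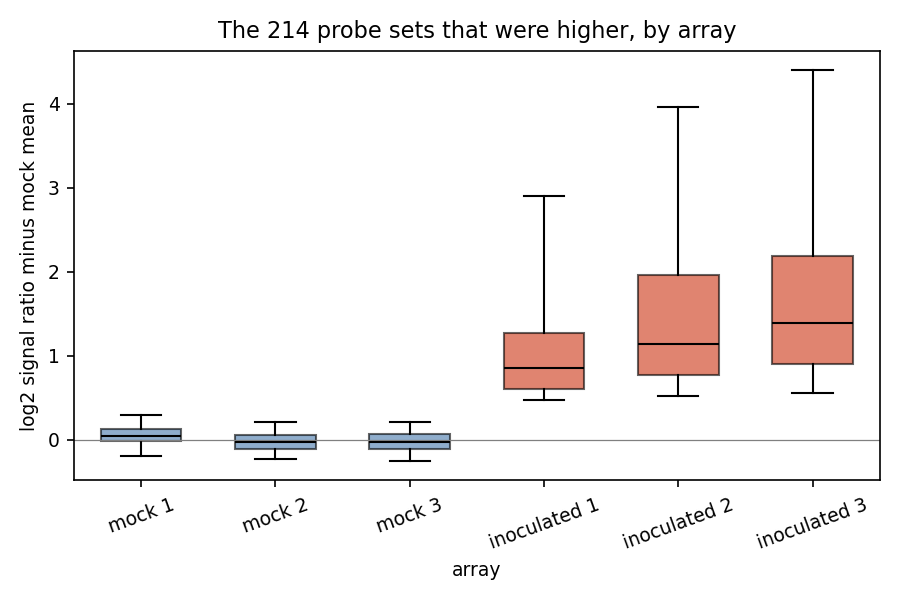
Log2 signal ratio minus the mock mean (vertical axis) over the 214 probe sets that were higher, for each of the 6 arrays (horizontal axis). Boxes span the quartiles with the median as a line, and whiskers reach the 5th and 95th percentiles; medians are 0.85, 1.14 and 1.39 on inoculated replicates 1, 2 and 3.

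Control transcripts on the array were compared between the groups with exact two-sided permutation tests, for which 3 arrays against 3 give no p below 0.1. The mean log2 ratio of ubiquitin was 0.04 higher in the inoculated samples (exact p = 0.3), that of GAPDH 0.03 higher (exact p = 0.8), and those of actin and elongation factor 1-alpha 0.04 lower (exact p = 0.8 and 0.5). Sucsyn and G-6-PDH, as the array names them, were 0.22 and 0.15 higher (exact p = 0.2 for each), CYP86 was 0.11 lower (exact p = 0.6), and 18S rRNA was 0.21 higher (exact p = 0.7). The adjusted p over these 8 transcripts was 0.8 for each. The log2 signal at the 3′ end minus that at the 5′ end, which reads differences in RNA integrity between arrays, had a median over 7 transcripts of 0.02 ± 0.11 (SD, n = 3) in the mock and -0.03 ± 0.05 in the inoculated samples (exact permutation p = 0.5). Each probe set is centred on its own median, so values near 0 do not show that the RNA was intact. Bacterial hybridisation controls, which are added in fixed amounts before hybridisation, had a median ratio of 2.24 on inoculated replicate 1 and between 0.68 and 1.02 on the other arrays. Poly-A spike-in controls had a median ratio of 0.63 on mock replicate 1 and between 0.97 and 1.19 on the others. Without mock replicate 1 and inoculated replicate 1, 414 probe sets were higher and 39 were lower.

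**Figure D3:**
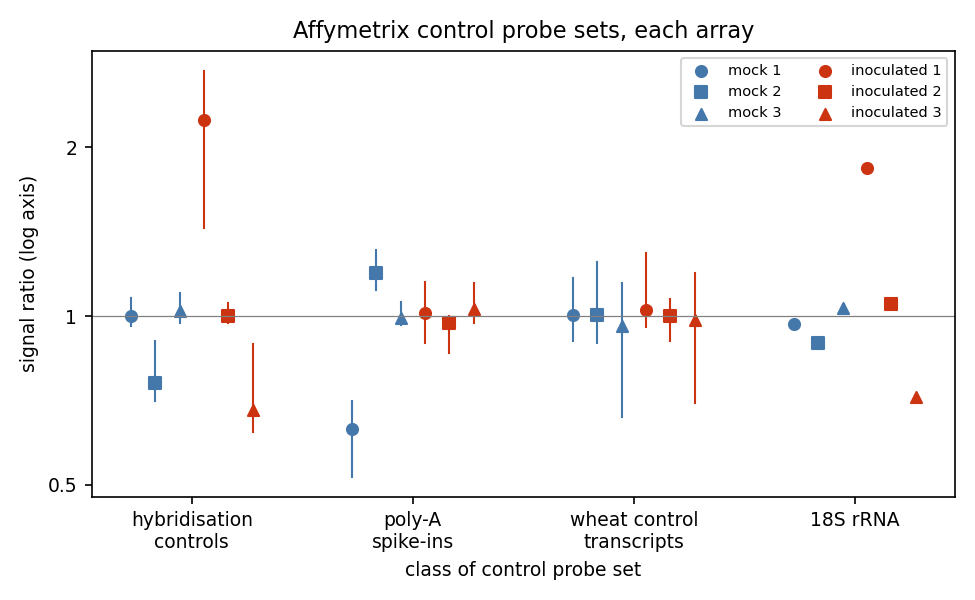
Signal ratio (vertical axis, log scale) of 4 classes of Affymetrix control probe sets (horizontal axis) on each array. Points are medians and lines the range over the probe sets of a class, blue for mock and red for inoculated; hybridisation controls reach a median of 2.24 on inoculated replicate 1 and poly-A spike-ins 0.63 on mock replicate 1.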

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

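All tests in this part were chosen after the results had been seen. Signals of the hybridisation controls and of 18S rRNA were highest on inoculated replicate 1, where the bacterial hybridisation controls had a median ratio of 2.24 against at most 1.02 on a mock array and 18S rRNA 1.84 against at most 1.03. Over the 6 arrays the log2 18S rRNA ratio followed the log2 hybridisation control ratio, with Pearson's r = 0.99 (exact permutation p = 0.0042, adjusted 0.0083) and Spearman's rho = 0.94 (exact permutation p = 0.017, adjusted 0.017), and r was 0.88 without inoculated replicates 1 and 3, the arrays farthest from the median. On inoculated replicate 1 the median ratios of bioB, bioC, bioD and cre were 2.40, 2.37, 2.07 and 1.53, the lowest bioB probe set (2.23) lay above the highest cre probe set (1.63), and wheat control transcripts lay at 1.03. On mock replicate 2 cre was also nearer 1 (0.87) than bioB, bioC and bioD (0.73 to 0.76), as on inoculated replicate 3 (0.82 against 0.66 to 0.69). On the other arrays all of these controls lay between 0.97 and 1.04. The p-values above include inoculated replicate 1, on whose high signals both classes were flagged, and 18S rRNA is read by 1 probe set. A scale factor of inoculated replicate 1 stays open for the 18S rRNA signal. The correlation goes with it, while cre lay apart from bioB, bioC and bioD, and the signal levels that would show saturation are not kept. No biological explanation was tested.

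For the smaller rise on inoculated replicate 1, a shift shared by the arrays numbered 1 is not settled. It would cancel in inoculated minus mock and leave number 1 a rise as large as the others. With probe sets chosen without both of these arrays, the rise for number 1 had a median of 0.50 against 1.02 for the others. This ratio of 0.49 (95% bootstrap interval over probe sets 0.45 to 0.52) was below what a shared shift would give. Mock replicate 1, left out when probe sets were chosen, lay a median of 0.18 above the other mock arrays, not below them. Mock replicates 2 and 3, left out likewise, lay at -0.005 and -0.01. The ratio was 0.94 (0.84 to 1.03) for number 2 and 1.56 (1.27 to 1.69) for number 3. Numbers 1, 2 and 3 were read over different sets of 414, 18 and 86 probe sets. In these sets the other pairs rose by medians of 1.02, 3.19 and 1.43, so the ratios are not like for like. The other pairs' rise was also measured on the arrays that chose the probe sets, which can raise it. The bootstrap intervals cover the probe sets of 1 pair of arrays, not the spread between pools, for which 2 other pairs are too few. One common scaling of every change on inoculated replicate 1 stays open: scatter about a single slope was 0.40 and 0.53 against replicates 2 and 3 (177 and 99 probe sets, slopes 0.69 and 0.60), a mean of 1.14 times the 0.41 between those arrays, but the latter was over a different set of 46 probe sets with larger rises (slope 0.87). Over the same 214 probe sets for each pair, which were called partly for a small spread, it was 0.21 and 0.24 against 0.22, a ratio of 1.01 (95% bootstrap interval over probe sets 0.86 to 1.21). A weaker or later response in that pool of plants would also lower all rises together. This biological explanation is untested, and the scatter about a slope cannot separate it from a compressed array. On the inoculated arrays the rise ran opposite to the hybridisation control signal. The control ratio fell from 2.24 on replicate 1 to 0.68 on replicate 3, with replicate 2 between. Median rises over the 214 probe sets went from 0.85 on replicate 1 to 1.39 on replicate 3, again with replicate 2 between. The 18S rRNA ratio had the same order as the controls. An order of 3 arrays is too short to test, so an array effect also stays open.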

How the results depend on the processing

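The fits without probe sets divided by a floor and without both arrays numbered 1 were chosen after the data had been seen. The number of calls depended on the processing. Their direction says little about stability: every inoculated array lay beyond every mock array for all 224, which fixes the sign in each alternative other than the normalizations, and median centring moved no array by more than 0.014. With quantile normalization all 224 had the same direction. Leaving out 1 array gave 42 to 491 calls, with 42 to 463 higher and 0 to 28 lower; at 2-fold or more it gave 42 to 226, with 42 to 224 higher and 0 to 4 lower, and it gave 1 to 3 gene lists past the threshold. Without mock replicate 2, the fit with 0 lower calls, limma gave 3123 probe sets an unadjusted p under 0.05, 1413 of them lower. Array weights, which gave inoculated replicate 2 a weight of 6.64, called 1615 probe sets (1086 higher, 529 lower), and at 2-fold or more 198 (195 and 3); this moved the share of higher calls from 95.5% to 67.2%, and the cause was not tested. Without both arrays numbered 1 there were 453 calls (414 and 39), and at 2-fold or more 226 (216 and 10). The replicate block gave 284 calls, of which 194 were shared with the 224, and raised the lower calls to 31. Deviations of same-numbered arrays from their group means correlated at 0.22, 0.07 and 0.06, and 4 of 6 arrays correlated best with their own number. These few values, a hint from the data only, leave open whether the numbers pair the arrays. The trend with robust estimation gave 239 calls, 163 of them shared with the 224, and 21 lower calls, and quantile normalization gave 0 lower calls at 2-fold or more, with 8 lower calls in all and 1928 lower at an unadjusted p under 0.05. The trend alone gave 220 calls, median centring 221, and leaving out probe sets divided by a floor 221. Lists past the threshold numbered 2 with 1 probe set per gene, 3 without probe sets divided by a floor and 0 with an estimated correlation.

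Medians of lists that changed sign lay close to 0, and none of these lists was past the threshold with all arrays, though defence and grain proteins passed without inoculated replicate 3 (camera adjusted p = 0.022 for each, at the preset correlation). Array weights gave -0.0087 for defence proteins and 0.0036 for translation; leaving out cross-matching probe sets gave -8.7e-05 for defence proteins and -0.0089 for photosynthesis; 1 probe set per gene gave -0.0033 for photosynthesis; leaving out both arrays numbered 1 gave -0.052 for defence proteins, -0.030 for grain proteins and 0.0076 for translation. Leaving out 1 array gave medians from -0.0041 to 0.066 for inhibitor proteins, -0.022 to 0.050 for defence proteins, -0.018 to 0.030 for photosynthesis, -0.037 to 0.020 for rbcL and -0.026 to 0.0025 for fructan, starch and sugar enzymes. Filters on low signal, lists of members above a signal percentile and other pseudocounts were not run, because row-centred ratios hold no level. The arrays' number and the lost signal level limit the precision, and no value over background is kept.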

Other observations

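The odds ratio, the counts by cluster and the reading of the share of higher calls under the alternatives were tests chosen after the results were seen. The count over splits of the arrays was planned. So were the alternatives, except the fits without probe sets divided by a floor and without both arrays numbered 1. Of the annotated genes not described above, 8 rose. LOC543498 was 1.98-fold higher, LOC542993 1.92-fold, LOC543201 1.86-fold, LOC543197 1.82-fold, LOC543317 1.79-fold, LOC606365 1.60-fold, LOC100125708 1.56-fold and LOC542830 1.46-fold. Of these genes, 4 had other probe sets, none of which passed: LOC543498 had a log2 difference of -0.05 (limma adjusted p = 0.96), LOC542993 of 0.90 (0.27) and 0.15 (0.79), LOC606365 of 0.33 (0.47) and LOC542830 of 0.59 (0.070). Probe sets whose IDs share a stem were counted as a cluster, and only clusters with at least 3 calls are given. Among those without a gene, all 4 of the cluster Ta.8582 rose, with log2 differences from 1.02 to 2.38, as did all 3 of Ta.22564, from 2.67 to 3.51. In 3 further clusters with at least 3 calls, not all members passed: 3 of 4 did in TaAffx.28047, from 0.81 to 4.37, and 3 of 5 in both Ta.23348, from 0.89 to 1.41, and Ta.21353, from 0.64 to 0.92, all higher. All 3 probe sets of TaAffx.18447 fell, with log2 differences from -0.67 to -0.65, and they account for 3 of the 10 falls.

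Annotated probe sets were called more often than the rest, 25 of 1273 (1.96%) against 199 of 59906 (0.33%), an odds ratio of 6.01 (95% interval 3.78 to 9.18; Fisher's exact test, two-sided p = 1.28e-11). Probe sets of one gene are not independent, which this test leaves out. The reason for the difference was not tested.

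Calls were almost all higher, 95.5%. Median centring gave 95.5%, 211 of 221, but it moved the median log2 difference over all probe sets only from -0.010 to -0.0036, so it leaves open whether the arrays' scaling holds an offset. Quantile normalization gave 97.4% and array weights 67.2%. The asymmetry was stronger among larger differences: at an unadjusted p under 0.05, limma gave 2188 higher and 1992 lower probe sets, and of these 186 and 4 differed by 2-fold or more. Of the 10 splits of the 6 arrays into 3 and 3, only the real one, 1 of 10, gave calls, 224 against at most 0 in another, which are too few splits for a share under 0.05. At an unadjusted p under 0.05 the real split gave 4180 probe sets and the others 1195 to 5203, the highest being mock replicate 1 with inoculated replicates 1 and 2.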
